A study of Mus musculus with 78 samples.

How the data were processed

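The values analysed were gene expression in 30 RNA-seq libraries of mouse embryos and CpG methylation in E6.5 epiblast lacking Tet1 and Tet2. Expression values were deposited as FPKM, made by mapping reads to mm9 with TopHat2 2.0.11 and summing with Cufflinks 2.0.2, per the submitters' processing notes. Bases were called with CASAVA 1.8. Methylation values were deposited as whole-number read counts per CpG position and strand, methylated and unmethylated, from 3 libraries merged by the authors after mapping to mm9 with BS-Seeker2 and Bowtie2, versions not given. The epiblast came from matings of mice heterozygous for the Tet1 deletion and homozygous for that of Tet2, per the labels' protocols. No expression values from those embryos were used here, so loss of Tet1 and Tet2 was not checked.

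RNA of E3.5 and E4.0 came from cells lysed directly after superovulation and immunosurgery, and RNA of E5.5 to E7.5 from naturally mated mothers through a column kit, per the labels' protocols. Culture used a medium with 20% fetal bovine serum. For culture of 1 and 2 days the labels name whole embryos, while the protocol describes isolation of the inner cell mass, and column names carry an earlier day than the protocol. These libraries are called embryos throughout. Of the 78 samples, 45 had no processed table used here: 36 of STEM-seq, 7 of Hi-C and 2 of MethylC-seq. Their data are not analysed here.

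The 3 expression tables held 22613 genes for 22 libraries in vivo, 22590 for 4 libraries of culture for 4 days and 22592 for 4 libraries of 1 and 2 days. In the first, 27 gene symbols had been turned into dates and 4 lines repeated a symbol, and these were left out. Values of 1e-06 or less were set to 0. Of 22563 genes shared by the 3 tables, 13493 with at least 1 FPKM in at least 2 libraries were tested. The model was limma 3.58.1 in R 4.3.3 on log2(FPKM+1), with a mean-variance trend, 15 groups in 1 fit and 15 residual degrees of freedom. Adjusted p is the Benjamini-Hochberg value within a comparison. Calls needed an adjusted p under 0.05 and a log2 fold of at least 1 in size. Of 16 planned comparisons 14 were tested. The 2 that cross separately made tables, cultured against E6.5 epiblast and cultured against E6.5 visceral endoderm, were not, because table and condition cannot be told apart. E7.5 tissues were each set against the mean of the other 3.

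Gene sets were 30 lists of lineage markers, pathways and cell types that a sample could hold besides its own. They were tested with camera at a preset correlation between genes of 0.01 and again with the correlation estimated. Comparisons, tests, lists and most alternatives were fixed before the data were examined. Array weights, and leaving out a library for list tests, were added after the spread between replicates was seen. Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, quantile normalization, a term for replicate number, a fit on only the groups compared, and each library left out in turn. A lone remaining library was then assumed to vary like the other groups.

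Genes named were, per comparison, the 6 with the largest rise and the 6 with the largest fall among called genes with a mean of at least 10 FPKM in the higher group and libraries of the groups not overlapping, up to 4 members of a list by adjusted p, and genes that write or remove DNA methylation. Symbols of the Gm, Rik, Mir and Snor kinds were passed over, and so were LOC, AI and BC symbols, pseudogenes and symbols that are database identifiers. Genes whose call ended when a library was left out were passed over too, unless that is stated. A few genes that met the rule are not reported here.

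Methylation was summed as methylated over all reads, with Wilson intervals at 95%. Classes of CpGs used positions with at least 5 reads. Low regions were runs of at least 5 kb of 1 kb bins, each with at least 5 covered CpGs and a level under 20%. These steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. With a mean of 2.30 reads per position, single CpGs were not compared. Depth per expression library is unknown, since FPKM carry no counts.

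The pipeline was tested on simulated data. In the 13 direct comparisons limma recovered 9 to 28% of genes given a 2-fold change and 68 to 91% of those given a 4-fold change, and in the difference of differences 2% and 32%. Between 0 and 9 unchanged genes were called per comparison. Simulated values had the same spread for a gene in every group, and only genes with a mean log2 value above 3 were changed. In the data, the SD of the log2 difference between replicates ran from 0.258 (E7.5 mesoderm) to 1.11 (culture for 1 day). The simulation thus does not measure how many false calls the noisier groups gave. In simulated methylation, 3 of 3 planted regions were found, with all 37 kb of them. Those regions ended on bin edges and had evenly spaced CpGs, a single low level and even depth. This was an easy test, which does not measure how many regions are missed in the data.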

Results

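The series followed mouse embryos from the blastocyst to gastrulation and asked how DNA methylation, expression and chromatin folding change as the first lineages form. It held 78 samples: 39 of STEM-seq, which reads DNA methylation from few cells, 30 of RNA-seq, 7 of Hi-C, which maps contacts within chromatin, and 2 of MethylC-seq from embryonic stem cells. The expression tables covered E3.5 inner cell mass and trophectoderm, E4.0 inner cell mass, epiblast and visceral endoderm of E5.5 and E6.5, and ectoderm, primitive streak, mesoderm and endoderm of E7.5. Embryos flushed from the uterus at E4.5 and cultured for 1 or 2 days, and epiblast and visceral endoderm dissected from embryos after 4 days of culture, made up the remaining groups. For DNA methylation, the values came from E6.5 epiblast lacking Tet1 and Tet2, the enzymes that oxidise methylated cytosine, with 3 libraries merged into a single table. The other 45 samples were not analysed here.

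Each of the 15 expression groups had 2 libraries, and the FPKM of a group is given as mean ± SD over them. The files hold FPKM with no read counts, so how deeply each library was sequenced is not known from them. Summed over a library, the values came to between 272055 and 486836 FPKM in vivo. Sums ran from 354191 to 405412 FPKM after 4 days of culture and from 535833 to 580771 after 1 or 2 days. Paired libraries correlated with r from 0.898 (culture for 2 days) to 0.994 (E7.5 mesoderm) over log2(FPKM+1) values. The sample descriptions do not say whether paired libraries came from separate litters, so every p-value here measures the spread between these samples. Of 1285 genes at 20 FPKM or more in at least 29 libraries, 0 were listed at 0 in the remaining library. A gene listed at 0 throughout a group is given without a fold all the same. Folds were taken on the log2(FPKM+1) scale, which understates them for genes with low values. A gene is said to have risen or fallen where limma gave an adjusted p under 0.05 and a log2 fold of at least 1 in size. The 3 expression tables were made separately, so tests stayed within a table, apart from a comparison of differences that were each taken inside their own table. Of the gene lists tested with camera, 140 were called over all comparisons, and 31 of these held when the correlation between list members was estimated from the data.

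At E3.5, inner cell mass and trophectoderm differed at the genes that mark the first lineage decision. Tdgf1, a Nodal co-receptor, stood at 439 ± 21.6 FPKM in inner cell mass and 0.0905 ± 0.0139 in trophectoderm (log2 fold 8.65, limma adjusted p = 1.8e-04). The uridine phosphorylase gene Upp1 went from 0.874 ± 0.651 FPKM in trophectoderm to 569 ± 17.8 in inner cell mass (log2 fold 8.29, limma adjusted p = 1.54e-08). Rises were also seen in the naive factors Spic, at 195 ± 43.3 against 2.34 ± 0.872 FPKM (log2 fold 5.88, limma adjusted p = 8.9e-11), and Esrrb (log2 fold 3.61, limma adjusted p = 1.39e-07). Trophectoderm instead carried the lineage factor Gata3 at 159.7 ± 33.9 FPKM against 9.15 ± 1.40 (log2 fold -3.98, limma adjusted p = 2.26e-07), and Id2 at 991 ± 198 against 43.8 ± 15.8 (log2 fold -4.50, limma adjusted p = 5.6e-07). The whole comparison called 2333 genes, 1287 higher and 1046 lower in inner cell mass. In the trophectoderm list, 2 of 18 rose, 12 fell and 4 were not called (2 and 13 with the p adjusted over the list alone). Camera gave it adjusted p = 2.54e-07, and adjusted p = 0.154 with an estimated correlation. Bmp4 went against the name of that list, at 44.2 ± 9.21 FPKM in inner cell mass and listed at 0 in trophectoderm. For primitive endoderm genes, 10 of 17 rose, 2 fell and 5 were not called (12 and 2 with the p adjusted over the list alone), and camera gave adjusted p = 5.06e-04, and adjusted p = 0.288 with an estimated correlation. Sparc was among them at 169 ± 22.0 FPKM in inner cell mass (log2 fold 5.30, limma adjusted p = 7.93e-09). Dab2, of the same list, was higher in trophectoderm, at 169 ± 28.4 FPKM (log2 fold -4.29, limma adjusted p = 7.73e-04). Among naive pluripotency genes, 7 of 15 rose, 1 fell and 7 were not called (9 and 1 with the p adjusted over the list alone), with camera adjusted p = 8.15e-05, and adjusted p = 0.288 with an estimated correlation. Of the 7 called lists, 0 held with an estimated correlation. Fewer genes were called without inner cell mass replicate 1, inner cell mass replicate 2 or trophectoderm replicate 1, and more without trophectoderm replicate 2. A group left with 1 library has a wider error, so a drop alone does not show dependence on that library. Fitted alone, these 4 libraries gave 888.

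Between E3.5 and E4.0, the inner cell mass gained primitive endoderm and glycolytic genes. Trh, which encodes a hormone precursor, went from 1.05 ± 0.201 to 297 ± 32.6 FPKM (log2 fold 7.18, limma adjusted p = 1.52e-05). The Nodal antagonist Lefty2 went from 1.35 ± 0.457 to 161 ± 2.44 (log2 fold 6.12, limma adjusted p = 1.32e-05). Sox7, a primitive endoderm factor, was listed at 0 in E3.5 inner cell mass and reached 68.0 ± 9.45 FPKM at E4.0, while Foxa2 rose from 0.502 ± 0.199 to 17.0 ± 6.29 (log2 fold 3.54, limma adjusted p = 3e-05). Dppa3, of the naive pluripotency list, dropped from 1324 ± 92.7 to 30.8 ± 1.87 FPKM (log2 fold -5.38, limma adjusted p = 5.83e-06). Bhmt, a methyl transfer enzyme of methionine metabolism, dropped from 166 ± 72.0 to 0.637 ± 0.320 (log2 fold -6.61, limma adjusted p = 5.42e-10). The keratins Krt8 (log2 fold -4.09, limma adjusted p = 3.92e-05) and Krt18 (log2 fold -4.02, limma adjusted p = 5.72e-06) fell, Krt18 from 106 ± 35.1 to 5.85 ± 3.58 FPKM. Limma called 2778 genes, 2130 higher and 648 lower at E4.0. Of primitive endoderm genes, 11 of 17 rose, 0 fell and 6 were not called (11 and 0 with the p adjusted over the list alone), and camera gave adjusted p = 0.00214, and adjusted p = 0.584 with an estimated correlation. Trophectoderm genes fell as a list: 1 of 18 rose, 8 fell and 9 were not called (1 and 8 with the p adjusted over the list alone). Camera put that list at adjusted p = 3.1e-05, and adjusted p = 0.211 with an estimated correlation. In glycolysis, 9 of 17 rose, 0 fell and 8 were not called (10 and 0 with the p adjusted over the list alone), and camera gave adjusted p = 4.59e-04, and adjusted p = 0.255 with an estimated correlation. Its members included the phosphofructokinase gene Pfkl (log2 fold 4.29, limma adjusted p = 7.78e-08) and Ldha (log2 fold 3.46, limma adjusted p = 2.85e-07). Of stress and dissociation genes, 9 of 15 rose, 0 fell and 6 were not called (11 and 0 with the p adjusted over the list alone), with camera adjusted p = 0.00214, and adjusted p = 0.0440 with an estimated correlation. Egr1, an early response gene, went from 0.595 ± 0.111 to 48.0 ± 0.492 FPKM (log2 fold 4.94, limma adjusted p = 4.56e-08). Across all genes the median log2 difference was 0.27, and after quantile normalization the calls split into 1174 higher and 1192 lower. Without E3.5 inner cell mass replicate 2 the number fell to 1628.

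E5.5 epiblast had lost the naive program that the E4.0 inner cell mass still ran. Tfcp2l1 fell from 33.4 ± 2.91 to 0.136 ± 0.139 FPKM (log2 fold -4.92, limma adjusted p = 1.79e-07). Zfp42 fell from 166 ± 54.3 to 11.04 ± 0.403 (log2 fold -3.76, limma adjusted p = 7.47e-08), and the T-box factor Tbx3 from 44.2 ± 13.7 to 0.192 ± 0.221 (log2 fold -5.22, limma adjusted p = 3.46e-06). Spp1, a secreted matrix protein gene, went from 2057 ± 388 to 14.7 ± 3.71 FPKM (log2 fold -7.04, limma adjusted p = 1.65e-04). Gains included the tight junction gene Cldn6, at 215 ± 97.8 after 5.73 ± 5.31 FPKM (log2 fold 5.19, limma adjusted p = 2.1e-05). Others were the lactate dehydrogenase gene Ldhb, at 79.7 ± 16.0 after 0.774 ± 0.628 (log2 fold 5.54, limma adjusted p = 7.41e-04), and the Hippo pathway factor Tead2, at 59.0 ± 10.6 after 6.74 ± 0.0756 (log2 fold 2.94, limma adjusted p = 1.88e-05). Pou3f1, a neural factor, was listed at 0 at E4.0 and reached 9.22 ± 0.569 FPKM in E5.5 epiblast. A total of 2376 genes was called, 1170 higher and 1206 lower in epiblast. Naive pluripotency genes fell as a list: 0 of 15 rose, 13 fell and 2 were not called (0 and 14 with the p adjusted over the list alone). By camera the naive list had adjusted p = 2.36e-15, and adjusted p = 0.0262 with an estimated correlation. Primitive endoderm genes fell too, the E4.0 sample being whole inner cell mass, which includes that lineage. There, 0 of 17 rose, 16 fell and 1 were not called (0 and 16 with the p adjusted over the list alone), and camera gave adjusted p = 5.64e-16, and adjusted p = 0.0113 with an estimated correlation. Lamc1, a basement membrane gene, dropped from 42.5 ± 9.96 to 1.66 ± 0.431 FPKM (log2 fold -4.02, limma adjusted p = 3.53e-07). For glycolysis, 9 of 17 rose, 2 fell and 6 were not called (11 and 2 with the p adjusted over the list alone), with camera adjusted p = 6.53e-06, and adjusted p = 0.0780 with an estimated correlation. Tpi1 rose from 114 ± 17.2 to 675 ± 38.01 FPKM (log2 fold 2.56, limma adjusted p = 5.63e-06). Of stress and dissociation genes, Ddit3 included (log2 fold -3.80, limma adjusted p = 4.17e-06), 1 of 15 rose, 7 fell and 7 were not called (1 and 8 with the p adjusted over the list alone). Camera gave these adjusted p = 5.84e-05, and adjusted p = 0.00814 with an estimated correlation. Stage is tied to preparation here, because E4.0 cells came from superovulated mothers by immunosurgery and direct lysis and E5.5 cells from natural matings by column purification. With these 4 libraries fitted alone, 1056 genes were called.

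Few genes were called between E5.5 and E6.5 epiblast, the first genes of the primitive streak among them. Mixl1, a homeobox gene of the streak, went from 0.212 ± 0.0541 to 39.8 ± 1.28 FPKM (log2 fold 5.07, limma adjusted p = 3.59e-04). Wnt8a went from 0.159 ± 0.0349 to 4.53 ± 0.268 (log2 fold 2.25, limma adjusted p = 9.36e-05). Mesp1, a factor of nascent mesoderm, was listed at 0 at E5.5 and stood at 4.29 ± 0.612 FPKM at E6.5. Dppa4 fell from 69.6 ± 9.22 to 7.23 ± 0.904 FPKM (log2 fold -3.10, limma adjusted p = 6.82e-04), and the testis gene Tsx from 25.2 ± 10.99 to 0.753 ± 0.386 (log2 fold -3.85, limma adjusted p = 3.86e-04). The germline antigen gene Mageb16 fell from 13.2 ± 3.57 to 0.449 ± 0.0262 (log2 fold -3.27, limma adjusted p = 8.14e-06), and the nucleic acid sensor Zbp1 from 16.0 ± 3.05 to 0.121 ± 0.171 (log2 fold -3.92, limma adjusted p = 9.79e-05). Germline genes went down as a list: 0 of 16 rose, 5 fell and 11 were not called (0 and 8 with the p adjusted over the list alone). The camera result was adjusted p = 5.44e-18, and adjusted p = 0.00120 with an estimated correlation. Among primitive streak genes, 5 of 16 rose, 0 fell and 11 were not called (6 and 0 with the p adjusted over the list alone), with camera adjusted p = 2.91e-08, and adjusted p = 0.134 with an estimated correlation. In all, 132 genes were called, 58 higher and 74 lower at E6.5. With array weights the split turned, with 541 genes called, 316 higher and 225 lower. In simulated data this comparison recovered 10% of genes given a 2-fold change, so smaller changes would mostly be missed. The median log2 difference over every gene was 0.105, and calls split 67 to 106 after quantile normalization. The number called rose without E5.5 replicate 1 and fell without E5.5 replicate 2, E6.5 replicate 1 or E6.5 replicate 2. A fall can also come from the wider error of a group left with 1 library. Fitted on these 4 libraries alone, limma called 0 genes, so none of those named above, although 2054 had an unadjusted p under 0.05.

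Epiblast and visceral endoderm of E5.5 gave the largest number of calls of any pair. Pou5f1, the pluripotency factor, stood at 355 ± 142 FPKM in epiblast and 0.383 ± 0.150 in visceral endoderm (log2 fold 7.95, limma adjusted p = 1.85e-06). Pim2, a growth kinase gene, stood at 710.3 ± 6.19 against 6.63 ± 3.95 (log2 fold 6.65, limma adjusted p = 1.01e-05). Visceral endoderm carried the serum protein genes: Ttr, the thyroxine carrier, at 1024 ± 178 FPKM against 2.71 ± 1.15 (log2 fold -8.13, limma adjusted p = 2.89e-10). Apoa1 was there at 2058 ± 729.9 against 9.78 ± 2.48 (log2 fold -7.55, limma adjusted p = 1.82e-05), and Afp at 193 ± 69.4 against 0.193 ± 0.273 (log2 fold -7.31, limma adjusted p = 1.01e-09). Among imprinted genes, H19 was high in visceral endoderm, at 297 ± 19.3 FPKM against 1.21 ± 0.281 (log2 fold -7.08, limma adjusted p = 1.65e-08). Snrpn was instead high in epiblast, at 211 ± 13.0 against 1.66 ± 1.09 (log2 fold 6.38, limma adjusted p = 5.8e-07). Limma called 4958 genes, 3663 higher and 1295 lower in epiblast. In the visceral endoderm list, 0 of 19 rose, 18 fell and 1 were not called (0 and 18 with the p adjusted over the list alone), and camera gave adjusted p = 7.6e-26, and adjusted p = 5.44e-04 with an estimated correlation. Lysosome and endocytosis genes serve the uptake of maternal nutrients by visceral endoderm. Of these, 0 of 15 rose, 12 fell and 3 were not called (0 and 12 with the p adjusted over the list alone), with camera adjusted p = 1.36e-10, and adjusted p = 0.0541 with an estimated correlation. The protease gene Ctsh was at 286 ± 43.8 FPKM in visceral endoderm (log2 fold -6.86, limma adjusted p = 1.42e-07). Genes of the primitive streak list were higher in visceral endoderm, Mixl1 (log2 fold -5.03, limma adjusted p = 1.03e-05) and Eomes (log2 fold -3.99, limma adjusted p = 6.9e-06) among them. Gsc, Lhx1 and Foxa2 are members of both this list and the anterior visceral endoderm list. Of the primitive streak list, 0 of 16 rose, 9 fell and 7 were not called (0 and 9 with the p adjusted over the list alone). Its camera result was adjusted p = 2.68e-06, and adjusted p = 0.143 with an estimated correlation. Higher values in epiblast ran through most genes: the median log2 difference was 0.36, and quantile normalization split the calls 2424 to 2215.

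At E6.5 the same tissues were separated by the same serum protein genes and by signalling antagonists of the anterior visceral endoderm. Cer1, a secreted inhibitor of Nodal and BMP, reached 438 ± 21.1 FPKM in visceral endoderm against 0.992 ± 0.792 in epiblast (log2 fold -7.84, limma adjusted p = 2.21e-07). The Wnt inhibitor Dkk1 reached 176 ± 54.1 against 1.10 ± 0.305 (log2 fold -6.37, limma adjusted p = 7.52e-08), and the homeobox gene Hhex 90.9 ± 12.4 against 0.503 ± 0.112 (log2 fold -5.93, limma adjusted p = 5.35e-07). Apoa1, at 3988 ± 296 FPKM, stood at 7.03 ± 8.02 in epiblast (log2 fold -9.45, limma adjusted p = 1.98e-06), and Afp, at 915 ± 18.0, at 1.32 ± 1.73 (log2 fold -8.86, limma adjusted p = 3.78e-11). Epiblast kept Pou5f1 at 389 ± 73.8 FPKM against 11.5 ± 13.3 (log2 fold 5.55, limma adjusted p = 1.43e-04). The sterol genes Idi1, at 96.6 ± 9.92 against 17.1 ± 2.00 (log2 fold 2.43, limma adjusted p = 1.39e-05), and Sqle, at 54.9 ± 6.35 against 11.9 ± 0.584 (log2 fold 2.11, limma adjusted p = 0.00167), were higher in epiblast. So was the imprinted Nnat, at 69.6 ± 9.16 against 4.24 ± 3.23 (log2 fold 3.90, limma adjusted p = 6.45e-05). Limma called 2231 genes, 938 higher and 1293 lower in epiblast. In the anterior visceral endoderm list, 0 of 10 rose, 9 fell and 1 were not called (0 and 9 with the p adjusted over the list alone), and camera gave adjusted p = 8.53e-11, and adjusted p = 0.0811 with an estimated correlation. In the wider visceral endoderm list, 0 of 19 rose, 19 fell and 0 were not called (0 and 19 with the p adjusted over the list alone), with camera adjusted p = 4.39e-37, and adjusted p = 6.66e-05 with an estimated correlation. Of general pluripotency genes, 6 of 12 rose, 0 fell and 6 were not called (6 and 0 with the p adjusted over the list alone). They had a camera result of adjusted p = 0.00415, and adjusted p = 0.513 with an estimated correlation. The 2 visceral endoderm libraries held Pou5f1 at 20.9 and 2.10 FPKM. Without E6.5 epiblast replicate 1 the calls numbered 1477, and without visceral endoderm replicate 2 they numbered 1372.

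Values of most genes in visceral endoderm were higher at E6.5 than at E5.5. Limma called 3670 genes, 3334 higher and only 336 lower at E6.5. The arginine methyltransferase gene Prmt1 rose from 2.94 ± 0.408 to 79.3 ± 16.1 FPKM (log2 fold 4.34, limma adjusted p = 5.29e-05), and the fibrinogen gene Fgb from 22.6 ± 2.20 to 91.9 ± 5.22 (log2 fold 1.98, limma adjusted p = 2.65e-05), a log2 fold of 0.97 after quantile normalization. Bri3, a membrane protein gene, fell from 67.3 ± 15.9 to 4.62 ± 0.835 FPKM (log2 fold -3.59, limma adjusted p = 5.29e-05), and Lars2, the mitochondrial leucine tRNA synthetase, from 5207 ± 47.6 to 147 ± 99.3 (log2 fold -5.33, limma adjusted p = 1.69e-05). The libraries also differed as wholes: values summed to 272055 and 329462 FPKM at E5.5 and 455957 and 445769 at E6.5, and ribosomal protein genes held 13.8 and 12.4% and 7.83 and 6.23% of those sums. Over every gene the median log2 difference was 0.50, and over genes with a mean of 10 FPKM or more it was 1.12. After quantile normalization 1633 genes were called, 610 higher and 1023 lower at E6.5, so how the libraries were scaled decided which direction was the larger. One list was called, neural ectoderm, in which 0 of 15 rose, 2 fell and 13 were not called (0 and 2 with the p adjusted over the list alone). Camera gave it adjusted p = 0.0182, and adjusted p = 0.877 with an estimated correlation. Its camera result was downward although its median member moved by 0.05 and its mean by -0.03. In the visceral endoderm list, 5 of 19 rose, 0 fell and 14 were not called (5 and 0 with the p adjusted over the list alone), but the list was not called, with camera adjusted p = 0.320, and adjusted p = 0.877 with an estimated correlation. Leaving out E5.5 replicate 1 gave 1827 genes, and leaving out E6.5 replicate 2 gave 2066.

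**Figure D1:**
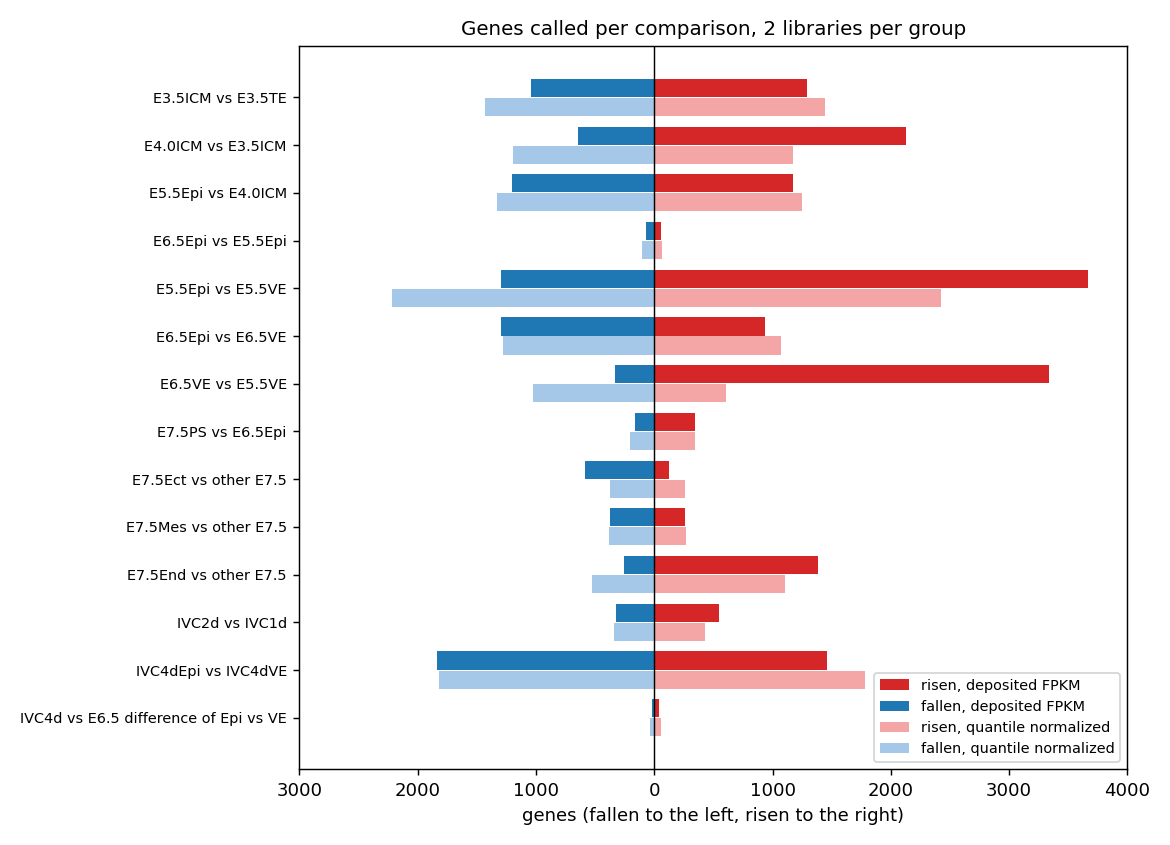
Genes called higher and lower in each of the 14 comparisons tested with limma, from the deposited FPKM and after quantile normalization.

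In the E7.5 primitive streak, many Hox, Wnt and mesoderm genes stood above their levels in E6.5 epiblast. Hoxb1 went from 0.119 ± 0.0970 to 143 ± 6.71 FPKM (log2 fold 7.005, limma adjusted p = 1.12e-13). Aldh1a2, which makes retinoic acid, went from 0.0571 ± 0.0159 to 133 ± 21.2 (log2 fold 6.98, limma adjusted p = 1.28e-10), and the homeobox gene Nkx1-2 from 0.597 ± 0.259 to 144 ± 8.63 (log2 fold 6.51, limma adjusted p = 3.58e-13). T, the brachyury factor of the streak, rose from 5.11 ± 1.57 to 314 ± 16.6 FPKM (log2 fold 5.71, limma adjusted p = 1.07e-08). Wnt3a rose from 0.0784 ± 0.00633 to 56.7 ± 4.81 (log2 fold 5.74, limma adjusted p = 3.58e-13), and Tbx6 from 0.219 ± 0.0462 to 100.5 ± 4.69 (log2 fold 6.38, limma adjusted p = 1.18e-11). Msgn1, a paraxial mesoderm factor, was listed at 0 in E6.5 epiblast and stood at 153 ± 51.4 FPKM in the streak. Utf1, a chromatin protein of pluripotent cells, dropped from 293 ± 3.99 to 6.43 ± 0.629 FPKM (log2 fold -5.31, limma adjusted p = 7.38e-07). The metallothionein genes Mt1, from 277 ± 52.0 to 7.56 ± 1.53 (log2 fold -5.02, limma adjusted p = 6.68e-09), and Mt2, from 184 ± 2.36 to 6.36 ± 0.695 (log2 fold -4.66, limma adjusted p = 1.21e-08), fell with it. The imprinted Peg3 rose from 14.2 ± 2.10 to 168 ± 8.04 FPKM (log2 fold 3.47, limma adjusted p = 4.56e-05). Limma called 504 genes, 345 higher and 159 lower in the streak. Of Hox genes, 5 of 8 rose, 0 fell and 3 were not called (5 and 0 with the p adjusted over the list alone), and camera gave adjusted p = 4.63e-27, and adjusted p = 8.06e-05 with an estimated correlation. Of Wnt signalling genes, 8 of 16 rose, 0 fell and 8 were not called (9 and 1 with the p adjusted over the list alone), with camera adjusted p = 1.93e-11, and adjusted p = 0.0354 with an estimated correlation. Of mesoderm genes, 7 of 22 rose, 0 fell and 15 were not called (8 and 0 with the p adjusted over the list alone), with camera adjusted p = 6.71e-15, and adjusted p = 2.33e-04 with an estimated correlation. Among general pluripotency genes, 0 of 12 rose, 4 fell and 8 were not called (0 and 5 with the p adjusted over the list alone), and camera gave adjusted p = 4.19e-07, and adjusted p = 0.212 with an estimated correlation. Fewer genes were called whichever of the 4 libraries was left out, by nearly the same amount. A group left with 1 library has a wider error, so this does not show dependence on any library. These 4 fitted alone gave 787.

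Against the other 3 tissues of E7.5, ectoderm stood out more by what it lacked. Aldh1a2 was at 0.723 ± 0.835 FPKM in ectoderm against 73.6 ± 57.1 over the other 6 libraries (log2 fold -4.89, limma adjusted p = 4.43e-09). The receptor gene Aplnr was at 3.29 ± 3.504 against 90.8 ± 42.8 (log2 fold -4.54, limma adjusted p = 6.44e-09), and Cer1 at 0.111 ± 0.156 against 160.4 ± 198 (log2 fold -5.07, limma adjusted p = 1.32e-05). Mesp1 was at 0.497 ± 0.0447 FPKM against 23.7 ± 20.8 (log2 fold -3.48, limma adjusted p = 6.57e-10) and Tbx6 at 1.14 ± 1.36 against 42.9 ± 45.4 (log2 fold -3.69, limma adjusted p = 6.44e-09). Ectoderm was higher for the chemokine gene Cxcl12, at 54.9 ± 24.1 FPKM against 3.91 ± 3.81 (log2 fold 3.84, limma adjusted p = 1.13e-07). It was higher too for Utf1, at 34.3 ± 2.14 against 3.01 ± 2.71 (log2 fold 3.41, limma adjusted p = 1.97e-05), and for the forebrain factor Lhx5, at 4.37 ± 0.407 against 0.201 ± 0.184 (log2 fold 2.17, limma adjusted p = 3.35e-07). Limma called 712 genes, 123 higher and 589 lower in ectoderm. Of neural ectoderm genes, 8 of 15 rose, 0 fell and 7 were not called (10 and 0 with the p adjusted over the list alone), with camera adjusted p = 2.12e-17, and adjusted p = 4.94e-04 with an estimated correlation. Of mesoderm genes, 0 of 22 rose, 15 fell and 7 were not called (0 and 16 with the p adjusted over the list alone), and camera put them at adjusted p = 7.9e-26, and adjusted p = 1.67e-05 with an estimated correlation. For the primitive streak list, 0 of 16 rose, 7 fell and 9 were not called (0 and 8 with the p adjusted over the list alone), with camera adjusted p = 4e-08, and adjusted p = 0.0693 with an estimated correlation. The median log2 difference over every gene was -0.21, and quantile normalization left 636 calls, 261 higher and 375 lower. Ectoderm replicate 2 had a ribosomal protein share of 17.3% against 8.06% in replicate 1. Limma called 1528 genes without replicate 1 and 288 without replicate 2.

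Mesoderm of E7.5 was set apart by heart, blood vessel and lateral mesoderm genes. Myl7, a cardiac myosin light chain, was at 347 ± 17.9 FPKM in mesoderm against 25.2 ± 18.1 over the other 6 libraries (log2 fold 4.00, limma adjusted p = 3.59e-06). Hand1 was at 188 ± 31.7 against 12.3 ± 6.52 (log2 fold 3.97, limma adjusted p = 1.3e-05), and the vascular receptor gene Kdr at 16.9 ± 0.518 against 0.566 ± 0.495 (log2 fold 3.58, limma adjusted p = 9.91e-14). Foxf1, at 12.0 ± 0.552 against 0.419 ± 0.329 (log2 fold 3.23, limma adjusted p = 1.9e-11), Bmp4, at 35.7 ± 4.51 against 2.43 ± 1.59 (log2 fold 3.55, limma adjusted p = 1.48e-06), and the imprinted Mest, at 489 ± 0.785 against 75.4 ± 27.4 (log2 fold 2.76, limma adjusted p = 0.00137), were also higher in mesoderm. Low there was the claudin gene Cldn6 at 3.46 ± 3.66 FPKM against 330.4 ± 367 (log2 fold -5.45, limma adjusted p = 1.31e-06). The cadherin gene Cdh1 was at 4.91 ± 2.90 against 119 ± 22.4 (log2 fold -4.41, limma adjusted p = 6.65e-07), and Cldn7 at 1.61 ± 1.09 against 87.0 ± 91.8 (log2 fold -4.38, limma adjusted p = 3.42e-07). Limma called 636 genes, 261 higher and 375 lower in mesoderm, and after quantile normalization 264 higher and 382 lower. In the mesoderm list, 18 of 22 rose, 0 fell and 4 were not called (19 and 0 with the p adjusted over the list alone), and camera gave adjusted p = 1.29e-43, and adjusted p = 4.96e-07 with an estimated correlation. Among Hox genes, 3 of 8 rose, 0 fell and 5 were not called (3 and 0 with the p adjusted over the list alone), with camera adjusted p = 4.95e-06, and adjusted p = 0.0366 with an estimated correlation. Hoxb6 was at 7.33 ± 1.796 FPKM in mesoderm (log2 fold 2.51, limma adjusted p = 5.31e-08). Of imprinted genes, 5 of 19 rose, 0 fell and 14 were not called (6 and 0 with the p adjusted over the list alone). Camera gave adjusted p = 1.52e-04, and adjusted p = 0.00856 with an estimated correlation. Without mesoderm replicate 1 the calls numbered 396, and without replicate 2 they numbered 353.

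The endoderm of E7.5 carried the serum protein genes of visceral endoderm together with genes of the definitive endoderm list. Apoa1 was at 3267 ± 42.6 FPKM in endoderm against 1.01 ± 1.21 over the other 6 libraries (log2 fold 10.84, limma adjusted p = 8.81e-09). Ttr was at 1199.5 ± 310.1 against 0.482 ± 0.732 (log2 fold 9.75, limma adjusted p = 1.04e-13). The retinol carrier gene Rbp4 was at 1668 ± 135 against 2.84 ± 1.48 (log2 fold 8.88, limma adjusted p = 2.39e-10), and Afp at 568 ± 14.1 against 0.149 ± 0.2002 (log2 fold 8.97, limma adjusted p = 4.17e-13). Foxa2, a pioneer factor of endoderm, was at 36.1 ± 6.63 FPKM against 0.439 ± 0.446 (log2 fold 4.73, limma adjusted p = 1.72e-08), and Cer1 at 412 ± 19.6 against 23.0 ± 36.7 (log2 fold 6.33, limma adjusted p = 1.24e-07). Lower in endoderm were Nkx1-2 at 2.31 ± 0.145 FPKM against 60.6 ± 66.1 (log2 fold -3.15, limma adjusted p = 2.51e-10) and Wnt8a at 0.715 ± 0.341 against 23.4 ± 25.0 (log2 fold -2.92, limma adjusted p = 2.25e-09). Limma called 1644 genes, 1384 higher and 260 lower in endoderm, and after quantile normalization 1105 higher and 527 lower. Among visceral endoderm genes, 19 of 19 rose, 0 fell and 0 were not called (19 and 0 with the p adjusted over the list alone), with camera adjusted p = 2.87e-40, and adjusted p = 4.03e-05 with an estimated correlation. Definitive endoderm genes followed, as 11 of 17 rose, 0 fell and 6 were not called (11 and 0 with the p adjusted over the list alone), and camera gave adjusted p = 1.21e-09, and adjusted p = 0.0286 with an estimated correlation. Among lysosome and endocytosis genes, 12 of 15 rose, 0 fell and 3 were not called (13 and 0 with the p adjusted over the list alone), with camera adjusted p = 1.05e-11, and adjusted p = 0.0370 with an estimated correlation. Their cargo adaptor gene Dab2 was at 543 ± 44.5 FPKM (log2 fold 5.93, limma adjusted p = 1.05e-06). Hox genes went the other way: 0 of 8 rose, 4 fell and 4 were not called (0 and 4 with the p adjusted over the list alone). For Hox genes camera gave adjusted p = 1.1e-09, and adjusted p = 0.0108 with an estimated correlation. Foxa2 and Cer1 are also members of the anterior visceral endoderm list, and E6.5 visceral endoderm held Cer1 at 438 ± 21.1 FPKM. Sox17, of the definitive endoderm list, was at 1.89 ± 0.0748 FPKM here and 2.01 ± 0.160 in E6.5 visceral endoderm. Outside their own group, both endoderm libraries correlated most with E6.5 visceral endoderm, at 0.957 and 0.962. The labels name only endoderm, so the shares of visceral and definitive endoderm cells in this sample are unknown.

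In the fit of all groups, embryos cultured for 2 days and for 1 day differed at endoderm genes and at other genes. Ttr went from 0.720 ± 1.02 to 30.6 ± 8.13 FPKM (log2 fold 4.32, limma adjusted p = 3.46e-06). Apom, an apolipoprotein gene, went from 0.238 ± 0.337 to 34.1 ± 8.59 (log2 fold 4.83, limma adjusted p = 2.29e-06), and Lgals2, a galectin gene, from 1.57 ± 2.21 to 39.5 ± 10.49 (log2 fold 4.29, limma adjusted p = 6.25e-04). The ribosomal protein gene Rpl22 fell from 54.9 ± 12.1 to 7.78 ± 5.08 FPKM (log2 fold -2.79, limma adjusted p = 1.8e-05), and the zinc finger gene Zfp382 from 13.1 ± 4.45 to 0.548 ± 0.775 (log2 fold -3.25, limma adjusted p = 4.9e-05). Limma called 871 genes, 551 higher and 320 lower after 2 days. In the visceral endoderm list, 5 of 19 rose, 0 fell and 14 were not called (7 and 0 with the p adjusted over the list alone). Camera placed it at adjusted p = 9.12e-05, and adjusted p = 0.374 with an estimated correlation. Among lysosome and endocytosis genes, 4 of 15 rose, 0 fell and 11 were not called (9 and 0 with the p adjusted over the list alone), and camera gave adjusted p = 7.64e-06, and adjusted p = 0.374 with an estimated correlation. Stress and dissociation genes moved in part, as 3 of 15 rose, 0 fell and 12 were not called (3 and 0 with the p adjusted over the list alone), with camera adjusted p = 0.748, and adjusted p = 0.988 with an estimated correlation. Of extraembryonic ectoderm genes, 2 of 12 rose, 0 fell and 10 were not called (2 and 0 with the p adjusted over the list alone), and camera gave adjusted p = 0.559, and adjusted p = 0.988 with an estimated correlation. Of the 6 called lists, 0 held with an estimated correlation. The paired libraries of 2 days correlated least of all groups, at r of 0.898, and the fit borrowed spread from the others. Both correlated more with 1-day replicate 2, at 0.917 and 0.913. The pair of 1 day correlated at 0.902, below the 0.917 of its replicate 2 with 2-day replicate 1. Pou5f1 was at 3.21 and 96.7 FPKM in the 2-day libraries, and Dnmt3a at 2.15 and 47.5 in those of 1 day. Whether the libraries differed in tissue content was not tested. Fitted alone, the 4 libraries gave 0 calls, with none of the genes above among them, and 697 genes at an unadjusted p under 0.05. Array weights left 29 calls, Ttr, Apom, Lgals2 and Zfp382 not among them. Without 1-day replicate 2 or 2-day replicate 1 limma called 2147 and 1807.

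After 4 days of culture, epiblast and visceral endoderm differed at the marker genes of these tissues. Pou5f1 was at 379 ± 15.7 FPKM in cultured epiblast and 0.864 ± 0.957 in cultured visceral endoderm (log2 fold 7.77, limma adjusted p = 2.49e-06). Sox2 was at 17.3 ± 1.87 and 0.0779 ± 0.110 (log2 fold 4.08, limma adjusted p = 5.84e-05), and Snrpn at 221 ± 22.4 and 1.62 ± 0.270 (log2 fold 6.41, limma adjusted p = 4.25e-07). Ttr, at 1124 ± 273 FPKM, Apom, at 579 ± 294, and Sox17, at 49.5 ± 7.24, in cultured visceral endoderm were listed at 0 in cultured epiblast. Ctsh stood at 619 ± 15.9 FPKM in visceral endoderm against 0.211 ± 0.299 (log2 fold -9.02, limma adjusted p = 2.58e-09). Gata4, an endoderm factor, was at 84.6 ± 16.1 against 0.201 ± 0.0197 (log2 fold -6.14, limma adjusted p = 2.28e-09), and the lipid transfer gene Mttp at 92.8 ± 31.0 against 0.198 ± 0.281 (log2 fold -6.27, limma adjusted p = 2.32e-10). Limma called 3300 genes, 1463 higher and 1837 lower in cultured epiblast, and 1619 with the 4 libraries fitted alone. In the visceral endoderm list, 0 of 19 rose, 18 fell and 1 were not called (0 and 19 with the p adjusted over the list alone), and camera gave adjusted p = 2.99e-24, and adjusted p = 7.72e-04 with an estimated correlation. Of primitive endoderm genes, 0 of 17 rose, 17 fell and 0 were not called (0 and 17 with the p adjusted over the list alone), with camera adjusted p = 2.18e-16, and adjusted p = 0.0109 with an estimated correlation. General pluripotency genes went up: 7 of 12 rose, 0 fell and 5 were not called (7 and 0 with the p adjusted over the list alone). Their camera result was adjusted p = 5.91e-04, and adjusted p = 0.517 with an estimated correlation.

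How culture altered the gap between epiblast and visceral endoderm was tested as the difference of the 2 within-table folds, culture minus E6.5. Limma called 59 genes, 39 positive and 20 negative. Cldn2, a tight junction gene, stood at 46.5 ± 3.77 FPKM in E6.5 visceral endoderm and 2.26 ± 0.768 in cultured visceral endoderm, beside 0.0861 ± 0.122 in E6.5 epiblast and a listing of 0 in cultured epiblast (limma adjusted p = 1.41e-05). The transporter gene Slc16a9 stood at 19.7 ± 1.70 and 0.845 ± 0.131 FPKM in visceral endoderm of the uterus and of culture (limma adjusted p = 1.82e-06). Sox17, a factor of primitive and definitive endoderm, went the opposite way, at 2.01 ± 0.160 FPKM in E6.5 and 49.5 ± 7.24 in cultured visceral endoderm (limma adjusted p = 0.00320). The redox gene Glrx was at 6.73 ± 0.312 and 209.6 ± 32.5 FPKM in cultured epiblast and visceral endoderm and 53.7 ± 2.80 and 268 ± 8.11 at E6.5 (log2 difference -2.46, limma adjusted p = 0.00581). Single members seldom passed, yet lists were called. Of primitive endoderm genes, 0 of 17 rose, 1 fell and 16 were not called (0 and 3 with the p adjusted over the list alone), and camera gave adjusted p = 6.58e-06, and adjusted p = 0.360 with an estimated correlation. Of lysosome and endocytosis genes, 0 of 15 rose, 0 fell and 15 were not called (0 and 0 with the p adjusted over the list alone). Camera had these at adjusted p = 1.57e-04, and adjusted p = 0.466 with an estimated correlation. Of the 9 called lists, 0 held with an estimated correlation. The number of genes was 36 without E6.5 visceral endoderm replicate 2, 39 without cultured epiblast replicate 1 and 246 without cultured visceral endoderm replicate 1. A pseudocount of 0.1 left 19 calls and ended those of Cldn2, Slc16a9 and Sox17.

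Cultured and uterine tissues came from tables made separately, so their FPKM are only set side by side. Pou5f1 was at 379 ± 15.7 FPKM in cultured and 389 ± 73.8 in E6.5 epiblast. Dnmt3b was at 599 ± 4.13 in cultured and 175 ± 8.77 in E6.5 epiblast, Dnmt3a at 34.1 ± 5.98 and 68.4 ± 4.75, and Trim28, a corepressor at imprinted loci, at 184 ± 16.2 and 53.9 ± 14.2. For visceral endoderm, Ttr was at 1124 ± 273 FPKM in culture and 726 ± 30.9 at E6.5, Afp at 67.4 ± 10.4 and 915 ± 18.0, and Sox17 at 49.5 ± 7.24 and 2.01 ± 0.160. Cer1 was at 8.97 ± 12.1 FPKM in cultured and 438 ± 21.1 in E6.5 visceral endoderm, and its 2 cultured libraries held 17.5 and 0.415. Lefty1, a Nodal inhibitor, was at 1.89 ± 2.67 in cultured and 207 ± 0.727 in E6.5 visceral endoderm. No p-value belongs to these pairs.

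**Figure D2:**
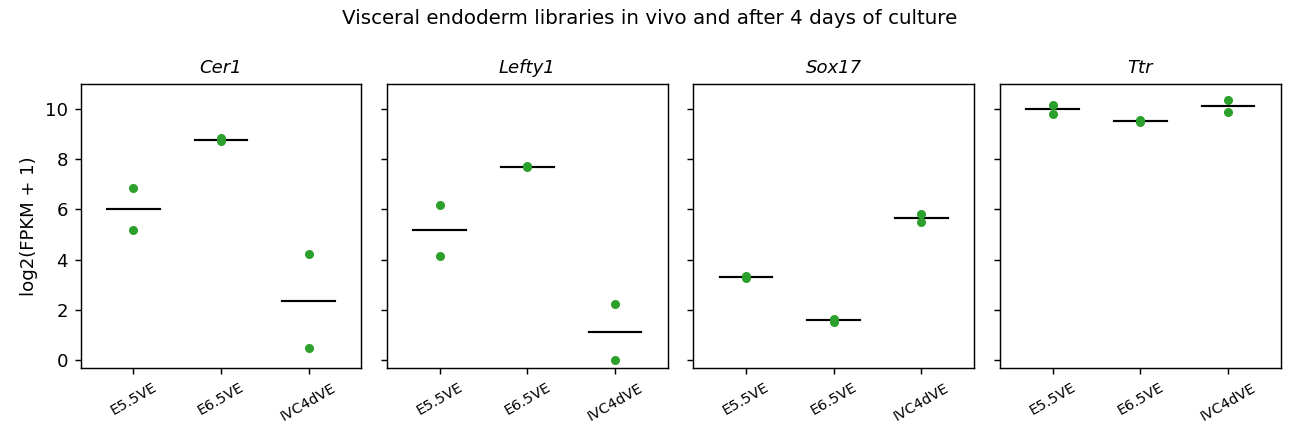
Values of Cer1, Lefty1, Sox17 and Ttr, as log2(FPKM+1), in each library of visceral endoderm from E5.5, E6.5 and 4 days of culture.

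Genes that write, maintain or remove DNA methylation changed with stage and tissue. Dnmt3l, the cofactor of the de novo methyltransferases, peaked in E4.0 inner cell mass: 24.3 ± 2.90 FPKM at E3.5, 445 ± 55.2 at E4.0 (log2 fold 4.14, limma adjusted p = 2.14e-04), 104.8 ± 47.6 in E5.5 epiblast and 6.15 ± 0.427 in E6.5 epiblast. The maintenance enzyme gene Dnmt1 rose from 4.69 ± 0.665 to 17.3 ± 1.87 FPKM over the same first step (log2 fold 1.69, limma adjusted p = 1.47e-04).

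Dnmt3b rose afterwards, from 16.1 ± 0.222 FPKM in E4.0 inner cell mass to 173 ± 28.3 in E5.5 epiblast (log2 fold 3.34, limma adjusted p = 8.35e-05), and stood at 175 ± 8.77 at E6.5. Tet2 fell over that interval from 11.1 ± 0.621 to 0.119 ± 0.0608 FPKM (log2 fold -3.44, limma adjusted p = 1.77e-05), while Tet1 was at 14.9 ± 1.29 and 13.1 ± 2.71 and Tet3 at 0.502 ± 0.379 and 1.32 ± 0.0128. Zfp57, which protects imprints, fell from 178 ± 0.600 to 8.14 ± 1.16 FPKM (log2 fold -4.30, limma adjusted p = 0.00320). Dnmt3a, at 18.4 ± 7.62 and 99.7 ± 2.54 FPKM, was not called (log2 fold 2.43, limma adjusted p = 0.0543).

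Within E5.5, epiblast exceeded visceral endoderm for Dnmt3l, at 104.8 ± 47.6 against 3.37 ± 3.92 FPKM (log2 fold 4.89, limma adjusted p = 1.57e-05), and for Dnmt3a, at 99.7 ± 2.54 against 5.74 ± 4.09 (log2 fold 4.05, limma adjusted p = 9.23e-04). The same held for Dnmt1, at 37.6 ± 3.85 against 8.07 ± 1.57 (log2 fold 2.10, limma adjusted p = 6.71e-06), and for the remodeller Hells, at 184 ± 12.2 against 25.6 ± 1.98 (log2 fold 2.80, limma adjusted p = 8.92e-04). Over genes with a mean of 10 FPKM or more, the median log2 difference of this pair was 0.92. Scaling of the E5.5 visceral endoderm libraries is open, so part of these folds may be common to most genes. At E6.5, mean FPKM in epiblast and visceral endoderm were 34.3 and 25.3 for Dnmt1 and 129 and 67.2 for Hells. They were 68.4 and 6.98 for Dnmt3a and 6.15 and 1.75 for Dnmt3l. At E7.5, Dnmt3b was at 64.3 ± 38.1 FPKM in ectoderm, 49.1 ± 8.62 in primitive streak, 12.8 ± 2.27 in mesoderm and 21.6 ± 4.09 in endoderm.

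At E3.5, inner cell mass held more Uhrf1, the partner of Dnmt1, than trophectoderm, at 52.9 ± 6.24 against 9.89 ± 3.62 FPKM (log2 fold 2.34, limma adjusted p = 8.02e-06), and more Tet1, at 17.8 ± 1.81 against 1.23 ± 0.141 (log2 fold 3.08, limma adjusted p = 2.21e-05).

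**Figure D3:**
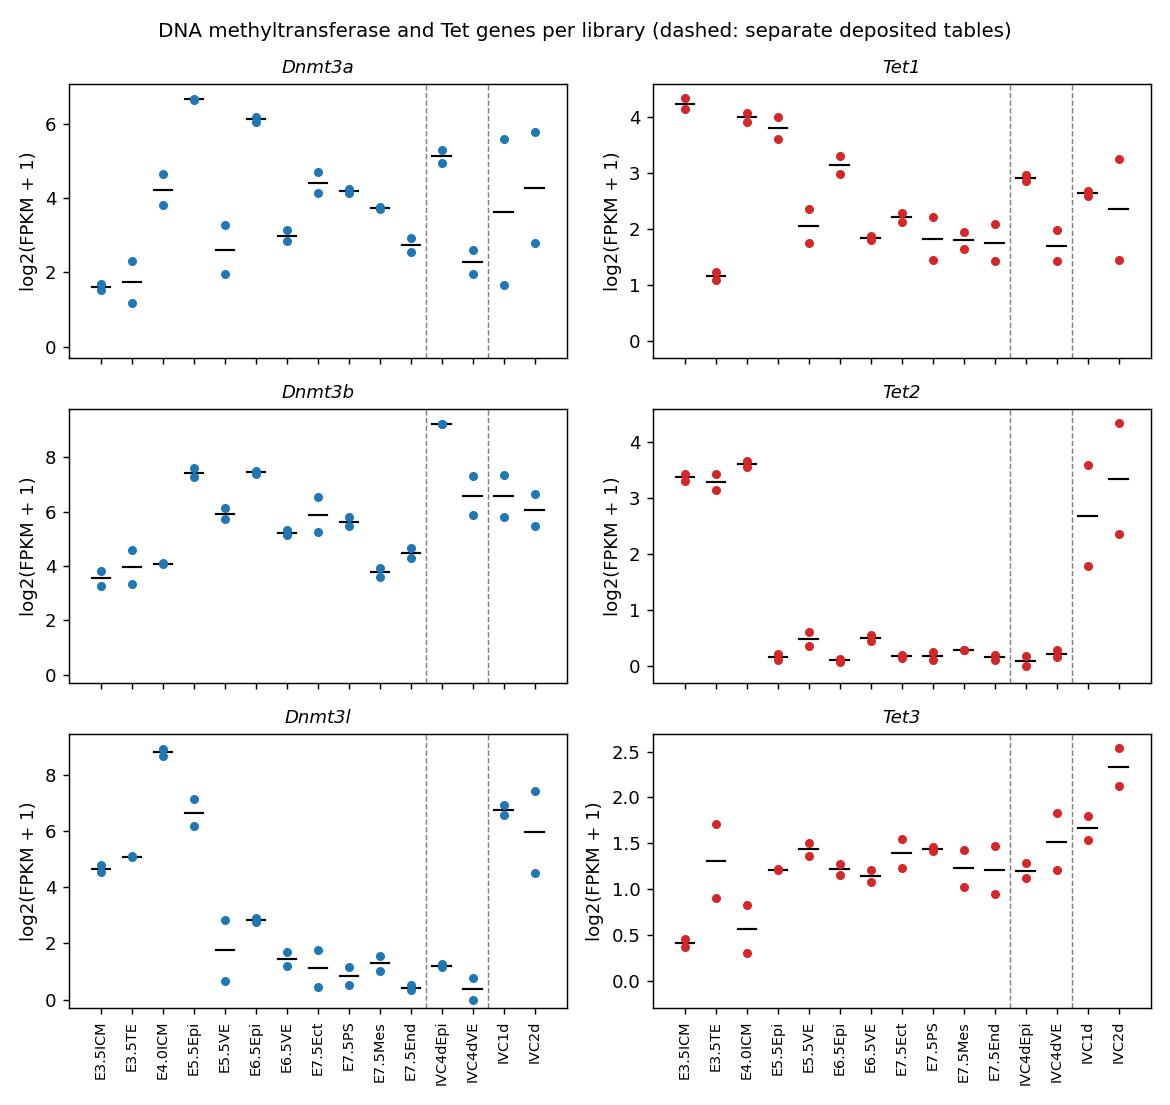
Values of Dnmt3a, Dnmt3b, Dnmt3l, Tet1, Tet2 and Tet3, as log2(FPKM+1), in each library by stage and tissue. Dashed lines part the tables that were made separately.

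DNA methylation of E6.5 epiblast lacking Tet1 and Tet2 was high across the genome. No expression values from these embryos were used here, so loss of Tet1 and Tet2 was not checked. Over all CpG positions, 81.12% of reads were methylated (Wilson 95% interval 81.11 to 81.13, which covers counting error only), with 2.296 reads per position and 75.3% of positions covered. Of CpGs with at least 5 reads, 65.3% were methylated above 80% and 3.83% below 20%. The 19 autosomes had a mean of 81.3 ± 1.24%, from 78.8% on chromosome 17 to 83.2% on chromosome 16. Chromosome X stood at 78.2%, below every autosome, and with 20 chromosomes ranked the smallest p such a rank can have is 0.05. Chromosome Y stood at 64.2%. The gap of X to the pooled autosomes was -3.06 points over all positions, -5.50 at positions with at least 5 reads and -18.1 at those with at least 10. Pooled levels weight each position by its reads, and 1730 positions with over 100 reads held 4.87% of all reads, and whether a few positions carry the last gap was not tested. The libraries were pooled and no wild-type values were used here, so these levels are descriptive and do not show what loss of Tet1 and Tet2 did.

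This epiblast held long stretches of low methylation. Runs of 1 kb bins below 20% methylation numbered 383 and spanned 2724 kb, 11 of them on chromosome X. The longest, 26 kb on chromosome 2 from 105506001 to 105532000, was methylated at 4.49% (3.52 to 5.72). Next came 21 kb on chromosome 5 from 140011001 to 140032000 at 3.67% and 21 kb on chromosome 17 from 86006001 to 86027000 at 3.87%. With a limit of 10% the number of regions was 196, and with a length of at least 10 kb it was 57. Coordinates are of the mm9 assembly, and no gene names were attached to them.

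**Figure D4:**
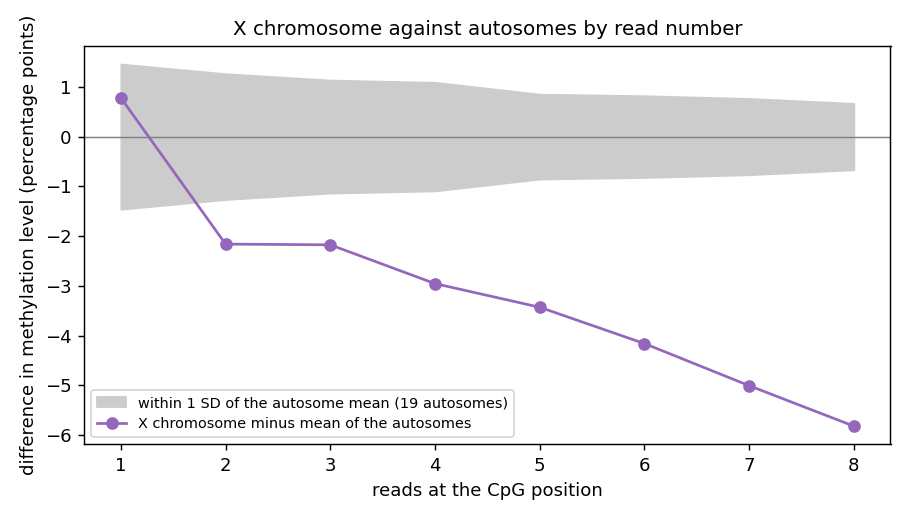
Methylation of the X chromosome minus that of the autosomes in E6.5 epiblast lacking Tet1 and Tet2, by the number of reads on each CpG.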

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

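The difference between culture and E6.5 was a planned comparison, but every test of an explanation in this part was chosen only after the result was seen. What drew attention was a test of the difference itself: for 59 genes the gap between epiblast and visceral endoderm after 4 days of culture differed from that of E6.5 (limma). A positive value means that the gap moved toward epiblast in culture.

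The log2 difference of differences was 6.15 for Lefty1, a Nodal inhibitor of the anterior visceral endoderm, -2.46 for Glrx and -2.45 for the hormone receptor gene Pth1r. Each of the other genes was listed at 0 throughout a group, and only its limma adjusted p is given. Toward epiblast these were Cer1 (0.0155), another Nodal inhibitor, Cldn2 (1.41e-05), the transporter gene Slc16a9 (1.82e-06), Zfp365 (0.0255) and the fibrinogen genes Fgb (0.00389) and Fga (0.00372), and away from it Sox17 (0.00320) and the colipase gene Clps (0.00140). Cldn2, Slc16a9, Fga, Fgb, Sox17, Clps and Glrx passed limma whichever library was left out. With a pseudocount of 0.1 the limma call of Glrx held and those of the other 10 genes named here ended, at an adjusted p of 0.261 for Cldn2, 0.145 for Slc16a9, 0.302 for Sox17, 0.409 for Lefty1 and 0.802 for Cer1. Fitted on only the groups compared, limma gave 0.230 for Cer1, 0.0736 for Lefty1, 0.142 for Zfp365, 0.131 for Pth1r, 0.0924 for Fga and 0.0736 for Fgb, which ended these calls. A filter at 5 FPKM ended those of Lefty1 (0.0691) and Pth1r (0.0776) in limma, and no filter that of Lefty1 (0.0696).

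The calls of the other 4 genes ended in some fits with a library left out. A group left with 1 library has a wider error, so a lost call does not show dependence on that library. For Lefty1 the log2 difference ran from 5.02 to 6.39 over the fits that ended its call. For Cer1 the limma adjusted p rose to 0.119 without E6.5 epiblast replicate 1, 0.0693 and 0.0863 without E6.5 visceral endoderm replicates 1 and 2, and 0.0706 and 0.0638 without cultured epiblast replicates 1 and 2. For Lefty1 it was 0.131 and 0.185 without E6.5 epiblast replicates 1 and 2, 0.167 and 0.148 without E6.5 visceral endoderm replicates 1 and 2, 0.186 and 0.128 without cultured epiblast replicates 1 and 2, and 0.212 without cultured visceral endoderm replicate 2. Zfp365 had 0.0630 and 0.148 without E6.5 epiblast replicates 1 and 2, 0.130 and 0.0954 without E6.5 visceral endoderm replicates 1 and 2, 0.190 without cultured epiblast replicate 1 and 0.0662 without cultured visceral endoderm replicate 2. Pth1r had 0.177 and 0.175 without E6.5 epiblast replicates 1 and 2, 0.209 and 0.102 without E6.5 visceral endoderm replicates 1 and 2, 0.232 without cultured epiblast replicate 2 and 0.171 without cultured visceral endoderm replicate 2.

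Camera called 9 lists for this difference, and 0 held with an estimated correlation, the lowest adjusted p then being 0.360. Toward epiblast were visceral endoderm (camera adjusted p = 1.5e-04), anterior visceral endoderm (3.38e-04), formative and primed epiblast (0.0123), FGF signalling (0.0118) and neural ectoderm (0.0499). Toward visceral endoderm were primitive endoderm (6.58e-06), lysosome and endocytosis (1.57e-04), cholesterol synthesis (3.38e-04) and oxidative phosphorylation (4.65e-04). A pseudocount of 0.1 turned the visceral endoderm list (0.993) and ended the calls of anterior visceral endoderm (0.535) and neural ectoderm (0.276), and quantile normalization ended that of neural ectoderm (0.0793). Without cultured visceral endoderm replicate 2 the camera adjusted p was 0.824 for anterior visceral endoderm, 0.443 for formative and primed epiblast, 0.354 for FGF signalling and 0.283 for neural ectoderm. Formative and primed epiblast had 0.05005 without E6.5 visceral endoderm replicate 1. Neural ectoderm had 0.0683, 0.163 and 0.103 without E6.5 epiblast replicate 1, E6.5 visceral endoderm replicate 1 and cultured epiblast replicate 2.

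Cer1 and Lefty1 were low in cultured visceral endoderm, Cer1 at 17.5 and 0.415 FPKM per library and Lefty1 at 3.78 and 0, and in the separately made table E5.5 visceral endoderm held Cer1 at 114 and 35.5 and Lefty1 at 72.0 and 16.5. Had the cultured samples only held fewer visceral endoderm cells, the whole visceral endoderm list would have moved with Cer1, but its median was 0.084 (SD 1.78, 19 genes). Fewer anterior visceral endoderm cells stay open: the 8 other members of that list had a median of 1.19 (SD 1.22), below Cer1, yet all 8 were higher in cultured replicate 1 than 2, by a median log2 of 2.76, as were Cer1 and Lefty1. For visceral endoderm an earlier stage stays open too. The spread of fold differences to E5.5 over that to E6.5 was 1.49 (1.17 to 1.67 over 64 choices of 1 library per group). That ratio cannot decide, because a different scaling of the E5.5 visceral endoderm libraries, left open below, would also widen the spread to E5.5. Cultured epiblast correlated with E5.5 at 0.930 to 0.941 and with E6.5 at 0.942 to 0.957. These values cannot decide on the stage of epiblast. The E5.5 epiblast pair agreed less (r of 0.972) than the E6.5 pair (0.985), which can lower correlations with E5.5 at any stage. The E5.5 values of Cer1 and Lefty1, above those of culture, go against an E5.5 stage of visceral endoderm for these genes. Cultured visceral endoderm correlated with E5.5 at 0.897 to 0.942 and with E6.5 at 0.918 to 0.938. Outside their own group, both its libraries correlated most with E5.5 replicate 2, at 0.942 and 0.928. That culture alters Nodal inhibitors themselves is only a hypothesis, and dissection or serum, neither tested, might account for it as well.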

How the results depend on the processing

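Most alternatives were planned; array weights, and list tests with a library left out, were chosen only after the result was seen. The 2 comparisons of cultured with E6.5 tissues were not run. For results that changed, the cause was not tested.

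Without 1 library at a time, the lowest and highest numbers of genes were 1444 and 2713 for E3.5 inner cell mass against trophectoderm, 1628 and 2231 for E4.0 against E3.5, 1627 and 1966 for E5.5 epiblast against E4.0, 32 and 275 for E6.5 against E5.5 epiblast, 3896 and 4540 for E5.5 epiblast against visceral endoderm, 1372 and 1705 for E6.5, and 1827 and 3474 for E6.5 against E5.5 visceral endoderm. They were 306 and 315 for primitive streak, 288 and 1528 for ectoderm, 353 and 641 for mesoderm, 1098 and 1741 for endoderm, 1034 and 2147 for culture of 2 days against 1, 2329 and 2954 for cultured epiblast against visceral endoderm, and 36 and 246 for the difference of differences. In all, 25 of 72 such fits moved the number by over 1.5 times. A group left with 1 library has a wider error, so a lower number alone does not show dependence on that library.

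Fitted on only the groups compared, limma called 888 genes for inner cell mass against trophectoderm, 1056 for E5.5 epiblast against E4.0, 0 for E6.5 against E5.5 epiblast (2054 at an unadjusted p under 0.05), 787 for primitive streak, 0 for culture of 2 days (697 at an unadjusted p under 0.05) and 1619 for cultured epiblast against visceral endoderm. A pseudocount of 0.1 gave 77 for E6.5 against E5.5 epiblast and 19 for the difference of differences. A filter at 5 FPKM gave 83, 334 and 21 for E6.5 against E5.5 epiblast, primitive streak and the difference of differences. Array weights gave 541, 1122, 456, 29 and 276 for E6.5 against E5.5 epiblast, primitive streak, ectoderm, culture of 2 days and the difference of differences. Quantile normalization gave 1633 for E6.5 against E5.5 visceral endoderm. No filter, and a term for replicate number, moved 0 of 14 counts by over 1.5 times.

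Of 140 list calls, 31 held with an estimated correlation. Over single genes, the call differed from the main fit without a turn in direction in 768 of 4528 tests with a library left out. On only the groups compared it was 239 of 928, with a pseudocount of 0.1 130 and with quantile normalization 66. The genes included writer and Tet genes near the threshold that the main fit did not call, which could have gained a call. Over single lists, 76 of 740 tests with a library left out lost the call. Replicate number as a term changed 15 gene calls and ended 3 list calls. In the difference of differences it ended those of Lefty1 (limma adjusted p = 0.0565), Pth1r (0.0506) and neural ectoderm (camera adjusted p = 0.0560). Between groups, residuals of like-numbered replicates correlated from -0.268 to 0.438. Results that turned direction were oxidative phosphorylation in ectoderm with quantile normalization (camera adjusted p = 0.700), the visceral endoderm list in the difference of differences with a pseudocount of 0.1 (camera adjusted p = 0.993), and Uhrf1 in E6.5 against E5.5 visceral endoderm with quantile normalization, at a log2 fold of -0.092 (limma adjusted p = 0.922).

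The methylation level was 80.7% as a mean over CpGs, 81.8% at CpGs with at least 5 reads and 74.2% with at least 10. The last is weighted by very deep positions: the mean over those CpGs was 81.7%. CpGs above 80% made up 64.3% with at least 10 reads and 71.8% with at least 1, and those below 20% 4.87% and 12.1%. X minus autosomes was -5.50 points with at least 5 reads and -18.1 with at least 10. Low regions numbered 196 below 10% and 57 at 10 kb or more. At 2.296 reads per position, depth limits how finely single CpGs can be classed.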

Other observations

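All tests of explanations in this part were chosen only after the result was seen, and the 2 patterns were picked from a longer list. Some germline genes rose into E5.5 epiblast. Syce1, a synaptonemal complex gene, went from 0.214 ± 0.302 FPKM in E4.0 inner cell mass to 6.06 ± 1.09 in E5.5 epiblast (log2 fold 2.55, limma adjusted p = 1.79e-06), and the sperm ATP carrier gene Slc25a31 from 0.141 ± 0.199 to 8.01 ± 2.98 (log2 fold 2.95, limma adjusted p = 3.49e-05). Of the germline list, 7 of 16 rose, 1 fell and 8 were not called (8 and 1 with the p adjusted over the list alone), and camera gave adjusted p = 0.00984, and adjusted p = 0.267 with an estimated correlation. The stages differ in preparation as well.

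Within E5.5, where preparation was shared, Hormad1, a meiotic chromosome gene, was at 16.7 ± 3.52 FPKM in epiblast and 0.172 ± 0.243 in visceral endoderm (log2 fold 3.92, limma adjusted p = 2.75e-05), and Stk31 at 7.83 ± 2.33 and 0.553 ± 0.266 (log2 fold 2.49, limma adjusted p = 4.62e-05). Here 10 of 16 rose, 0 fell and 6 were not called (10 and 0 with the p adjusted over the list alone), with camera adjusted p = 0.00530, and adjusted p = 0.223 with an estimated correlation.

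Far more genes were higher than lower in E6.5 than in E5.5 visceral endoderm, for which no biological explanation was tested. A few genes taking much of the FPKM at E5.5 might lower all others, yet with the 18 highest genes left out and the libraries rescaled the median log2 difference was 0.47, after 0.50 with them. Scaling between libraries remains open: summed values were lower at E5.5 (272055 and 329462 FPKM) than at E6.5 (455957 and 445769), and risen genes made up 37.4% of calls after quantile normalization, which would also remove a real common rise. Ribosomal protein genes held 13.8 and 12.4% of the sums at E5.5 and 7.83 and 6.23% at E6.5. The median log2 difference was 1.07 at 10 to 20 FPKM, 1.22 at 20 to 50, 1.22 at 50 to 100 and 1.07 at 100 to 200. These were nearly alike, much as a single factor per library would leave them. Only the 352 genes above 200 FPKM departed, at 0.53.

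The X chromosome was methylated below every autosome in E6.5 epiblast lacking Tet1 and Tet2. CpG density does not account for it: at equal density X stood -4.55 points from the autosomes, though in bins of 40 to 60 CpGs per kb it was the higher, at 40.2% against 24.7%. At positions with equal numbers of reads the gap, X minus autosomes, mostly stayed. It was -2.16 points at 2 reads, grew with each further read and reached -5.82 at 8, beyond the autosome SD of 0.667. Only at 1 read, the class tested first, was it within the SD, at 0.778 (SD 1.46). On X, 203657 positions had 1 read and 3032 had 8, and on the autosomes 4084690 and 212569. Positions with 8 reads were thus rarer on X and need not be alike, so these values cannot decide whether lower depth is the cause. An inactive X in female embryos might raise its densest bins, which stood at 11.1% against 6.62 to 9.14% on the autosomes, but no library of known sex was compared, so that is only an open hypothesis.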
